A study of Mus musculus with 6 samples.

How the data were processed

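The series holds RNA-seq libraries of mouse epiblast stem cells after 2 days of differentiation in serum, 3 labelled Mixl1 KO and 3 labelled Mixl1 induced. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were kept on irradiated mouse embryonic fibroblasts with bFGF at 10 ng/mL and Activin A at 20 ng/mL, aggregated in microwells for 24 h, and moved to plates that do not bind cells. Doxycycline at 1 µg/mL was given to the inducible line for the last 24 h. Libraries were made with a stranded poly(A) kit, per the labels' protocols.

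The authors deposited a table of raw read counts for each library, with 55471 gene identifiers and separate count columns for unstranded, sense and antisense reads. Per the submitters' processing notes, bcl2fastq, STAR and DESeq2 were used with the mm10 genome; versions and the gene annotation release are not given in the sources used here. The column of reads antisense to the first read was used, because it held 96.2% to 96.3% of the stranded gene reads, which fits the kit. Rows that name no gene (unmapped, multimapped, outside genes, ambiguous) took 15.1% to 17.6% of reads and were kept out of library sizes and tests. Multimapped reads were dropped from the counts, which lowers or loses genes with near-identical copies. Multimapped reads made up 7.43% to 7.66% of reads in knockout libraries and 6.79% to 6.97% in induced libraries.

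The authors also deposited a DESeq2 table for the comparison of the groups. It holds, per the file headers, a mean of normalised counts (a signal value), a log2 fold change with its standard error, a Wald score, p-values raw and adjusted, and a −log10 of the adjusted p. To find which counts it rests on, DESeq2 was run on each count column. The mean normalised count came within 1% of the authors' deposited value for 99.97% of 19805 genes with the unstranded column, and for 67.0% of 19434 genes with the antisense column. The deposited log2 fold changes therefore do not separate the strands: reads antisense to a gene can be counted for it, and reads where genes on opposite strands overlap are left out as ambiguous. The values computed here separate them.

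Gene identifiers were matched without their version number to GENCODE mouse release M21 (GRCm38, the mm10 assembly), which gave names, types and positions for 55144 of them. The unmatched rest held 0.0218% of gene reads. Where several identifiers share a symbol, the one with most reads kept it.

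Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion and group as its only term was fitted. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. Fold changes are induced over knockout. CPM values use the TMM-scaled library sizes. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Reads counted on genes ranged from 17490426 to 21026423 per library, and the median standard error of a log2 fold change was 0.084. Intervals for genes with 1 to 3 reads in a group are exact binomial intervals at 95% and cover counting error only.

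Gene lists (33, with 503 genes, of which 419 were tested) were fixed before the data were examined. The edgeR and list tests and the alternatives below were fixed then too, except where noted, and tests of single explanations were partly chosen later. Lists with at least 5 tested members were compared with all other genes by limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The genes to be named were also fixed by rule. They were Mixl1, then the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM in the higher group, groups that do not overlap, and symbols other than predicted models. From each list, up to 4 members past the threshold with the smallest p were added. Genes named outside this rule are marked as such, and some genes that meet it are not reported here.

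The median log2 fold change per chromosome was taken over tested genes. Windows of 5 Mb with at least 15 genes of at least 10 CPM were compared with 1000 shuffles of the gene positions. For GC content and length, a loess fit of the log2 fold changes was subtracted, over the 99.9% of tested genes with both values.

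The alternatives were DESeq2 1.42.0 size factors or upper-quartile factors, no filter or a filter of at least 1 CPM in at least 3 libraries, the unstranded counts, the replicate number as a term, leaving out each library in turn, DESeq2 and limma-voom as tests, a test against a 2-fold change, an adjusted p of 0.01, the other list tests, and chromosome medians over genes with at least 10 CPM or over genes that did not pass. Counts without the genes of chromosomes 15, 17 and 18 were added after the data were seen.

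The edgeR step was tested on simulated data for this comparison, with counts drawn for the 15091 tested genes and 200 of them changed. It recovered 73.1% of 67 genes changed by 0.5 on the log2 scale, 89.6% of 67 changed by 1 and 98.5% of 66 changed by 2. Of 14891 unchanged genes, 7 were called. In the real comparison 62.6% of genes passed, so the adjusted p was stricter in the simulation. Its counts were drawn with the trended dispersion, without a spread of dispersion between genes of like expression. Figures were drawn with matplotlib 3.10.9.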

Results

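RNA was sequenced from mouse epiblast stem cells that had been differentiated in serum as embryoid bodies for 2 days. Epiblast stem cells are pluripotent cells that resemble the epiblast of the embryo at the onset of gastrulation, and embryoid bodies are aggregates in which such cells differentiate. The 6 libraries formed 2 groups of 3, labelled Mixl1 KO and Mixl1 induced. Mixl1 encodes a homeobox transcription factor of the primitive streak, the site where mesoderm and endoderm form. In the induced group, a line with inducible Mixl1 had received doxycycline at 1 µg/mL for the 24 h before collection. The labels do not state whether the knockout cells received doxycycline or whether both lines share a parent. The line and Mixl1 thus differ together, and the drug may differ with them. Reads counted on genes ranged from 17490426 to 21026423 per library. Replicates of a group differed by more than counting noise, with a chi-square of 2.25 to 5.18 per degree of freedom, against 79.6 to 91.3 between groups. The labels call the samples triplicates without saying whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

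Mixl1 was higher in all 3 induced libraries. The gene lies on chromosome 1 from 180693043 to 180697034 of mm10, on the minus strand (ENSMUSG00000026497.7). The knockout libraries held 817, 668 and 812 reads of Mixl1, and the induced libraries 8860, 7720 and 7861. Expression was 39.8 ± 2.96 CPM (SD, n = 3; CPM, counts per 1e6 counts on tested genes after TMM scaling) in the knockout group and 432.5 ± 7.54 CPM (SD, n = 3) in the induced group, a 10.9-fold difference. The log2 fold change was 3.44 with a standard error of 0.055 (edgeR quasi-likelihood test, adjusted p = 1.66e-22). The labels do not name the altered part of the gene, and a count over the whole gene does not show which exons the knockout reads came from, so these reads neither check the knockout nor contradict it.

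The comparison asked which transcripts differ between cells with induced Mixl1 and cells labelled as its knockout. Of 15091 genes tested, 9450 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, with 4684 higher and 4766 lower in the induced group. A change of at least 2-fold was estimated for 2436 of them, 976 higher and 1460 lower, and a change of at least 8-fold for 407. A test against a 2-fold change called 1628 genes. The common biological coefficient of variation was 0.0485, and the first principal component separated the groups with 89.5% of the variance. Libraries of the groups did not overlap for 67.1% of tested genes, where chance gives 10% for 3 against 3.

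Among protein-coding genes, the largest rises included regulators and secreted proteins that were close to undetected in the knockout libraries. Lmo1, a LIM-only transcriptional cofactor, rose from 0.138 ± 0.025 to 80.6 ± 1.45 CPM (SD, n = 3; log2 fold change 9.11, SE 0.14). Nkx6-2, a homeobox factor of the ventral neural tube, rose from 0.103 to 60.6 CPM. Dbh, which makes noradrenaline from dopamine, had a log2 fold change of 8.64 (SE 0.28). Cer1, a secreted inhibitor of NODAL and BMP ligands in anterior endoderm, rose from 0.276 to 51.1 CPM. The homeobox gene Alx1 had a log2 fold change of 7.51, the matrix protein genes Optc and Spon1 7.92 and 6.81. Zfp951 and Xlr3b had 1 and 3 reads in all knockout libraries together, so their induced-to-knockout ratios of 652 (95% counting interval 117 to 25804) and 515 (176 to 2500) are loosely bounded. Both belong to families with similar copies, and reads that fit several copies were dropped.

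Slc38a4, an imprinted amino acid transporter gene, had the largest fall. It went from 406.4 ± 47.3 to 0.207 ± 0.088 CPM (SD, n = 3), a log2 fold change of -10.86 (SE 0.16). Cpxm2, a carboxypeptidase-like gene, fell from 96.6 to 0.070 CPM, and Grb10, an imprinted adaptor protein gene, from 689.4 to 3.31 CPM. Arg1, which encodes arginase, fell from 65.3 to 1.17 CPM; genes typical of macrophages, in which Arg1 can be abundant, were lower in the induced libraries too. Trim67, the BMP and WNT antagonist gene Sostdc1, the multiciliation gene Ccno and the desmosome gene Pkp1 had log2 fold changes of -5.79, -5.74, -5.38 and -5.37. Avpr1b, a vasopressin receptor gene, had 3 reads in all induced libraries together, and its knockout-to-induced ratio was 131 (95% counting interval 44.6 to 639). Eci3, a gene of fatty acid oxidation with similar copies, had a log2 fold change of -5.37. Each of the genes named in this and the preceding paragraph had an adjusted p of 1.11e-11 or less (edgeR).

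**Figure D1:**
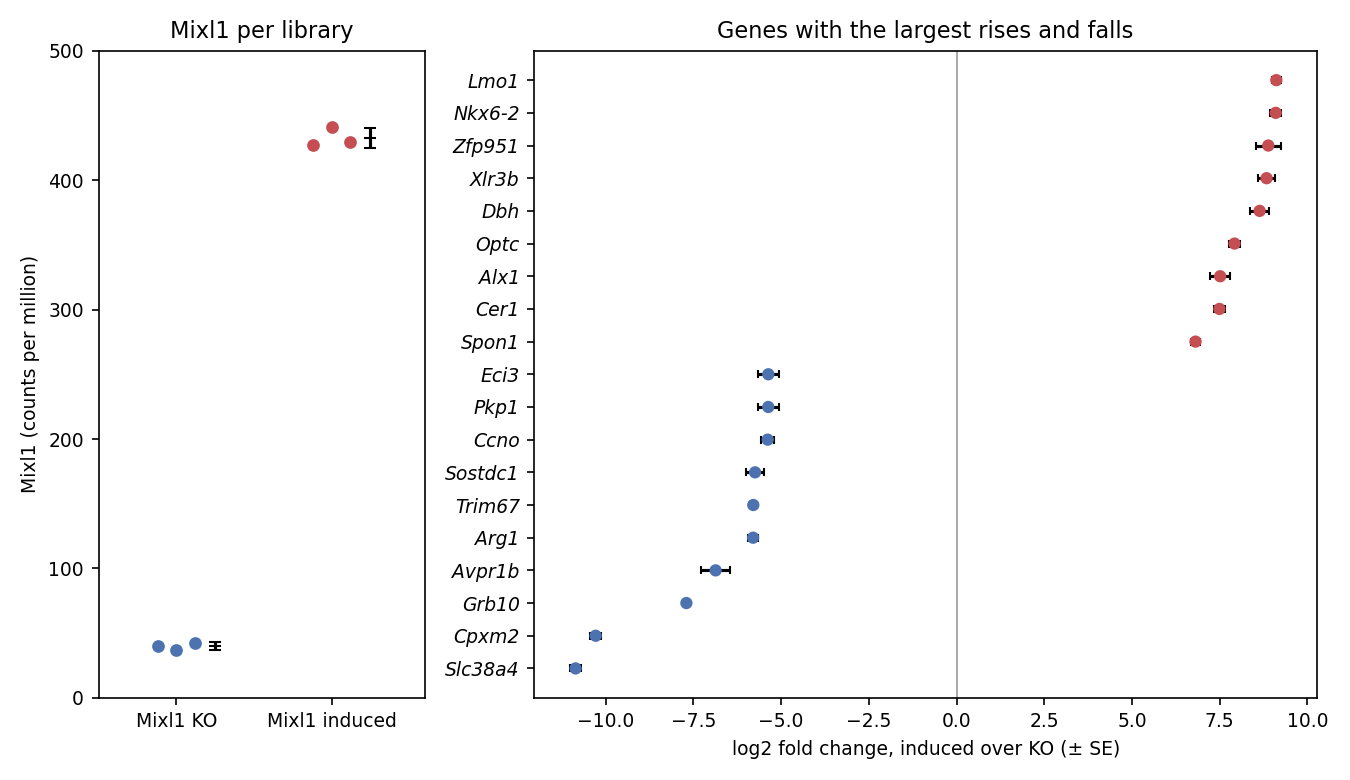
Left, Mixl1 in CPM for each of the 3 libraries per group, with the group mean and SD in black. Right, log2 fold change with its standard error for 9 of the protein-coding genes with the largest rises and the 10 with the largest falls under the naming rule, from 9.11 for Lmo1 to -10.86 for Slc38a4.

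Genes of the caudal epiblast and of neuromesodermal progenitors, the posterior cells that feed spinal cord and trunk mesoderm, were lower in the induced libraries. Of 13 tested members, 11 fell and 2 rose. T, the brachyury transcription factor gene, fell 8.82-fold from 1807 ± 50.4 to 204.8 ± 11.6 CPM (SD, n = 3). Wnt8a fell from 288.1 to 25.7 CPM, while Cyp26a1 and Sox2, a pluripotency and neural factor gene, rose, Sox2 from 51.7 to 187.6 CPM. Members that went against the direction of a list that passed are named here and below whatever their rank. The list's median log2 fold change was -2.41 (camera, adjusted p = 4.18e-05; adjusted p = 0.207 with an estimated correlation). Hox genes moved with it, 13 of 17 tested being lower and 1 higher, with Hoxa5 at -2.63, Hoxa3 at -2.19 and Hoxa2 at -1.87 on the log2 scale, and Hoxb13 at 0.71. Their median was -1.66 (camera, adjusted p = 0.00019; adjusted p = 0.207 with an estimated correlation).

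Primitive streak genes went both ways. T and Nkx1-2 (log2 fold change -2.41) were among 10 of 16 that fell, and Gsc, an organizer gene, and Cyp26a1, which degrades retinoic acid, were among 5 that rose. Gsc went from 1.16 to 25.2 CPM and Cyp26a1 from 13.8 to 67.0 CPM. The list did not pass (camera, adjusted p = 0.159), and its median of -0.42 and mean of 0.06 differed in sign.

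Definitive endoderm genes were higher as a group. Of 16 tested, 12 rose and 2 fell, with Cer1, Gsc, Gata6 and Gata4 in front. Gata6 went from 0.582 to 22.2 CPM and Gata4 from 0.474 to 12.1 CPM, and both encode zinc-finger factors of endoderm and of cardiac mesoderm. Trh and Sox7 fell, by 0.69 and 1.71 on the log2 scale. Sox17, the canonical definitive endoderm factor gene, did not pass the test, with a log2 fold change of 0.68, nor did Hhex at -0.06; these 2 were picked after their values were seen. The median was 1.04 (camera, adjusted p = 0.000274; adjusted p = 0.207 with an estimated correlation). Of 19 visceral endoderm genes only 7 were tested, with Afp and Ttr among those not tested. Of the 7, 4 fell, among them Cubn, Dab2 and Cited1, and Podxl rose by 0.23 on the log2 scale (camera, adjusted p = 0.379).

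Mesoderm and node genes went both ways within each list. Of 16 tested genes of paraxial and nascent mesoderm, 7 rose and 8 fell. Mesp1, an early mesoderm factor gene, rose from 2.27 to 32.0 CPM, Pdgfra from 14.6 to 42.7 CPM and Lfng from 25.5 to 97.2 CPM, whereas the somite gene Meox1 fell from 13.2 to 1.29 CPM (camera for the list, adjusted p = 0.756). Of 14 genes of lateral plate and cardiac mesoderm, 4 rose and 5 fell. Tbx20 (log2 fold change 3.82), Foxf1 (3.72) and Gata4 were higher (camera, adjusted p = 0.935). Tnnt2 (-3.31) and Bmp4 (-1.09), picked after their values were seen, were among those that fell. That list had a median of -0.10, a mean of 0.42 and the direction down in camera. Of 9 node and notochord genes, 3 rose and 5 fell, with Foxj1 at -2.47, Nog at -1.30 and Col2a1 at 1.54 (camera, adjusted p = 0.484).

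Tested blood and endothelial genes were mostly higher. Of 20 listed genes 10 were tested, and 7 of these rose and 2 fell. Gata1, Cd34 and Tie1 were among those not tested. Kdr, a VEGF receptor gene of early blood and vessel progenitors, rose from 2.71 ± 0.347 to 37.3 ± 1.19 CPM (SD, n = 3). Etv2, Tek and Gata2 had log2 fold changes of 3.36, 3.27 and 3.04, while Lmo2 (-1.37) and the vascular cadherin gene Cdh5 (-0.95) fell. The median was 1.12 (camera, adjusted p = 0.0211; adjusted p = 0.207 with an estimated correlation). This call was lost without knockout replicate 1 (adjusted p = 0.0622) and without induced replicate 1 (0.0532), 2 (0.112) or 3 (0.0943), where the median was between 0.70 and 0.92, and held without the other 2 libraries.

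**Figure D2:**
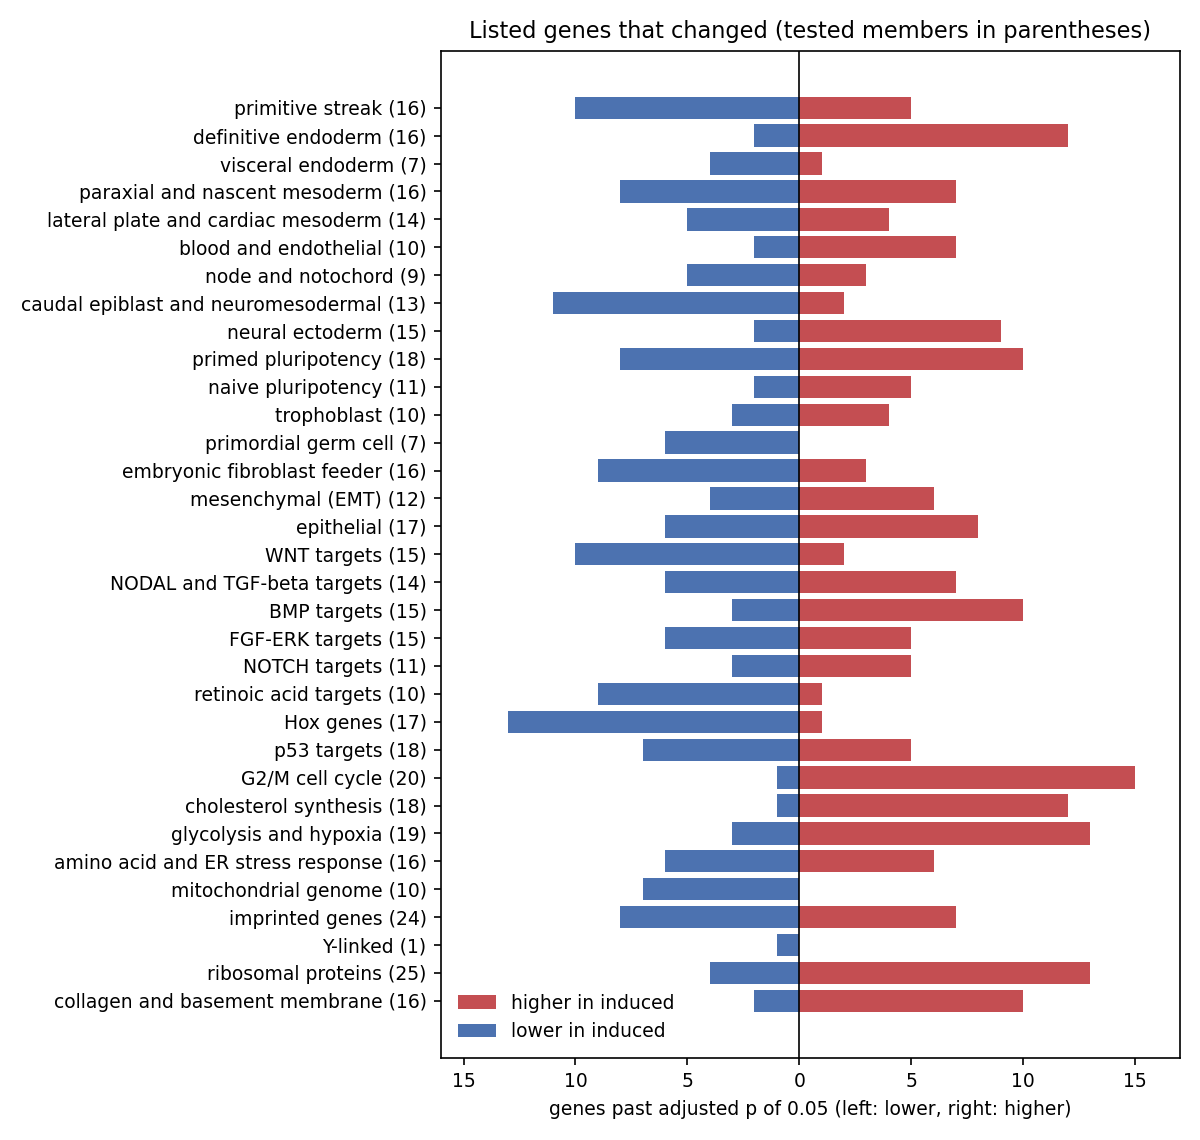
Number of genes in each fixed list that were lower (left) or higher (right) in the induced libraries at an adjusted p of 0.05, with the number of tested members in parentheses. In the caudal epiblast list 11 of 13 were lower, and in the definitive endoderm list 12 of 16 were higher.

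Neural ectoderm genes were mostly higher, 9 of 15 having risen and 2 fallen. The other 4, Pax3, Pax6, Zic1 and Lhx2, did not pass, with log2 fold changes of 0.28, 0.10, -0.49 and 0.43. They were picked after their values were seen. Irx3 rose from 6.45 to 70.1 CPM and Sox1 from 10.9 to 42.4 CPM, as did Sox2, while Sox3 (log2 fold change -3.28) and Nes, which encodes the intermediate filament nestin, fell, Nes from 317.5 to 167.9 CPM. The median was 0.43 (camera, adjusted p = 0.0257; adjusted p = 0.283 with an estimated correlation). All 18 primed pluripotency genes changed, 10 up and 8 down. Nanog fell from 161.3 to 53.5 CPM and L1td1 from 286.3 to 77.3 CPM, whereas Foxd3 rose from 0.921 to 18.5 CPM (camera for the list, adjusted p = 0.5). Of 11 naive pluripotency genes, 5 rose and 2 fell, with Nr0b1, Esrrb and Klf5 at 5.60, 3.45 and 0.97 and Klf2 at -2.05 on the log2 scale (camera, adjusted p = 0.111; adjusted p = 0.318 with an estimated correlation; 0.0253 with no filter on low counts).

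Of 7 tested primordial germ cell genes, 6 fell. Prdm14, picked after its value was seen, did not pass (log2 fold change -0.21, edgeR adjusted p = 0.251). Dnd1 fell from 51.9 to 12.5 CPM, Nanos3 from 3.10 to 0.752 CPM, Tfap2c from 145.4 to 39.5 CPM and Ifitm3 from 181.1 to 131.3 CPM. Tfap2c also marks trophoblast and epiblast. The median was -1.75 (camera, adjusted p = 0.000875; adjusted p = 0.207 with an estimated correlation). Of 10 trophoblast genes, 4 rose and 3 fell, with Gata3 at 3.83, Tfap2a at 2.36, Tfap2c at -1.88 and Ascl2 at -1.48 (camera, adjusted p = 0.935, direction down, against a median of 0.04).

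Genes that respond to WNT were mostly lower in the induced libraries. Of 15 tested, 10 fell and 2 rose. The other 3, Axin2, Rnf43 and Znrf3, did not pass, with log2 fold changes of -0.07, -0.23 and 0.07. They were picked after their values were seen. Notum, a secreted WNT inhibitor and feedback target, fell from 158.7 to 25.6 CPM and the caudal homeobox gene Cdx1 from 43.1 to 1.40 CPM. Dkk1, a secreted WNT inhibitor, rose from 2.07 ± 0.364 to 91.4 ± 10.0 CPM (SD, n = 3), and Lgr5 rose as well (log2 fold change 1.05). The median was -0.55 (camera, adjusted p = 0.000875; adjusted p = 0.207 with an estimated correlation). Retinoic acid targets were lower too, 9 of 10 having fallen, with Dhrs3 at -2.59 and Cdx1 shared with lists above, while Cyp26a1 rose. Their median was -1.37 (camera, adjusted p = 0.000512; adjusted p = 0.207 with an estimated correlation).

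BMP targets were mostly higher, 10 of 15 having risen and 3 fallen. Id4 rose from 5.43 to 17.1 CPM and Bambi from 42.4 to 84.7 CPM, and Gata2 and Gata3 belong to this list as well, while Bmp4 (-1.09), Nog (-1.30) and Grem1 (-0.96) fell. The median was 0.41 (camera, adjusted p = 0.017; adjusted p = 0.292 with an estimated correlation). Of 14 NODAL and TGF-beta targets, 7 rose, with Cer1, Gsc and Lefty1 (0.97) among them, and 6 fell (camera, adjusted p = 0.484). Lefty2 (-0.75) and Nodal (-0.38), picked after their values were seen, were among those that fell. FGF-ERK targets were mixed, 5 of 15 being higher and 6 lower, with Spry4 at 1.68 and Phlda1 at 1.46 against Etv4 at -1.66 and Etv5 at -0.63 (camera, adjusted p = 0.914). Of 11 NOTCH targets, 5 rose and 3 fell. Dtx4, Lfng, Hey1 and Notch1 had log2 fold changes of 2.06, 1.93, 1.69 and 1.04 (camera, adjusted p = 0.111; adjusted p = 0.52 with an estimated correlation; 0.0345 without induced replicate 1 and 0.00807 with no filter on low counts). The largest change in the list was a fall, Hes7 at -4.37, and Heyl fell by 1.66 on the log2 scale; these 2 were picked after their values were seen.

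**Figure D3:**
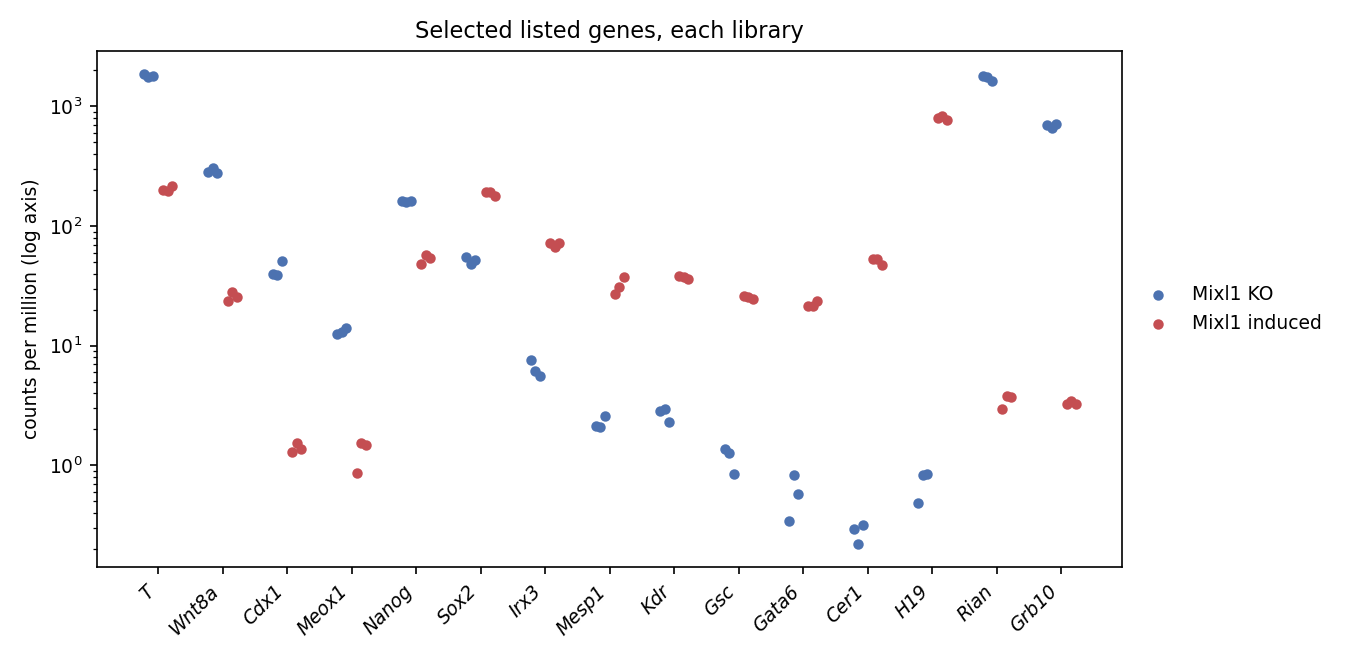
Expression of 15 named genes in each library, in CPM on a log axis, with knockout libraries in blue and induced libraries in red. T lies near 1807 CPM in the knockout and 204.8 CPM in the induced group, and the libraries of the groups do not overlap for any gene shown.

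Genes of the G2 and M phases were modestly higher, 15 of 20 having risen and 1 fallen. Ccnb1, Plk1, Cdc20 and Birc5 had log2 fold changes of 0.48, 0.45, 0.44 and 0.44, and Kif20a of -0.27. The median was 0.24 (camera, adjusted p = 0.00133; adjusted p = 0.322 with an estimated correlation). Glycolysis and hypoxia genes were higher in 13 of 19 cases and lower in 3. Ldha, the lactate dehydrogenase gene, rose from 833.7 ± 39.7 to 1926 ± 101.9 CPM (SD, n = 3), Pfkp from 40.7 to 88.0 CPM and Egln3 from 11.5 to 40.3 CPM, while Ndrg1 (-2.09), Bnip3 (-0.72) and Slc2a3 (-0.44) fell. The median was 0.53 (camera, adjusted p = 0.00335; adjusted p = 0.207 with an estimated correlation). Cholesterol synthesis genes were higher in 12 of 18 cases and lower in 1, with Sc5d at 0.54 and Dhcr7 at 0.52, and Idi1 at -0.42. The median was 0.27 (camera, adjusted p = 0.0121; adjusted p = 0.283 with an estimated correlation).

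Transcripts of the mitochondrial genome were lower, 7 of 10 having fallen. The other 3 did not pass, among them mt-Nd6, picked after its value was seen, which had the largest estimate of the list in the other direction (log2 fold change 1.43, adjusted p = 0.0685). The subunit genes mt-Nd1, mt-Nd2, mt-Nd4 and mt-Nd5 had log2 fold changes of -0.62, -0.75, -0.76 and -0.93. The median was -0.57 (camera, adjusted p = 0.0149; adjusted p = 0.48 with an estimated correlation). Collagen and basement membrane genes were higher in 10 of 16 cases and lower in 2. Fn1, the fibronectin gene, rose from 933.6 to 2213 CPM and Serpinh1, a collagen chaperone gene, from 1148 to 1908 CPM. Lama1 rose from 15.9 to 45.2 CPM and Plod2 by 1.10 on the log2 scale, while Lamb1 (-0.86) and Lama5 (-0.31) fell. The median was 0.50 (camera, adjusted p = 0.00657; adjusted p = 0.618 with an estimated correlation).

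Mesenchymal and epithelial genes each went both ways. Of 12 mesenchymal genes, 6 rose, including Fn1 and the integrin gene Itga5 (0.94), and 4 fell, including Vim (-0.94) and Tgfb1 (-0.51; camera, adjusted p = 0.379). Of 17 epithelial genes, 8 rose and 6 fell. The keratin genes Krt18 and Krt8 were at 1.21 and 1.00, and Cdh1, which encodes E-cadherin, and Esrp1 at -0.80 and -1.14 (camera, adjusted p = 0.864, direction up, against a median of -0.02). Of 18 p53 targets, 5 rose, with Plk2 at 1.54, Eda2r at 1.11 and Zmat3 at 0.54, and 7 fell, with Cdkn1a at -0.78 (camera, adjusted p = 0.914, direction up, against a mean of -0.10). Of 16 genes of the amino acid and ER stress response, 6 rose and 6 fell, with Psat1 at 0.43, Xbp1 at 0.37, Ddit4 at -0.92 and Atf3 at -1.83 (camera, adjusted p = 0.771, with a median of 0.01 and a mean of -0.19). Ribosomal protein genes, whose reads were dropped where they also fit processed pseudogenes, changed little. Of 25, 13 rose and 4 fell, with Rps18 at 0.46, Rpl27 at 0.25, Rpl18 at 0.24 and Rpl37 at -0.32 (camera, adjusted p = 0.111).

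Markers of other cell types moved with the groups. The cells are routinely grown on irradiated embryonic fibroblasts. Of 16 fibroblast genes, 9 fell and 3 rose, with Dcn at -2.64, Loxl1 at -1.44, Twist2 at -1.42 and Fbln2 at -1.08. Of the abundant fibroblast collagens, Col1a1 was at 309.7 and 185.3 CPM in knockout and induced libraries (log2 fold change -0.74) and Col1a2 at 95.1 and 201.9 CPM (1.09). The median of the list was -0.63 (camera, adjusted p = 0.0607; adjusted p = 0.687 with an estimated correlation), and it passed without knockout replicate 3 (0.0245), without induced replicate 1 (0.0345) or 2 (0.0378) and with no filter on low counts (0.00857). In a list of 18 macrophage genes, drawn up after the first results were seen but before these genes were looked at, all 17 tested fell, by 1.43 to 3.24 on the log2 scale. Their summed expression was 86.0, 124.8 and 101.7 CPM in the knockout libraries and 22.6, 22.2 and 19.3 CPM in the induced libraries. The macrophage genes fell together (camera, p = 9.48e-09; p = 0.0724 with an estimated correlation). Of the Y-linked genes only Ddx3y was tested, at 1.64 and 0.425 CPM (log2 fold change -1.94, adjusted p = 1.34e-05).

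Imprinted genes, which are expressed from either the maternal or the paternal chromosome, held some of the largest changes in the data. Of 24 tested, 7 rose and 8 fell, and the list as a whole had no direction (median -0.03; camera, adjusted p = 0.484). H19, a maternally expressed non-coding RNA, rose from 0.719 to 804.2 CPM (log2 fold change 10.13, SE 0.094). Mest, paternally expressed, rose from 279.7 to 2965 CPM. Rian, a maternally expressed RNA of the cluster between Dlk1 and Dio3 on chromosome 12, fell from 1740 ± 85.4 to 3.48 ± 0.464 CPM (SD, n = 3). Grb10 belongs to this list as well.

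Over the 32 lists with at least 5 tested members, 14 passed in camera with its preset inter-gene correlation of 0.01, 8 up and 6 down. None of the 14 passed with an estimated correlation, where their adjusted p-values ranged from 0.207 to 0.618. The self-contained test fry, which asks whether a list's genes move on balance in a common direction, called 30 of the 32 lists, and its mixed form, which asks whether they change at all, called 32. Adjusted over the list alone, the counts of changed genes were the same in 26 of 33 lists and larger by 1 gene in the other 7.

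Changes were uneven along the genome. The median log2 fold change of the 596 tested genes on chromosome 15 was -0.33, and 367 of them were lower against 82 higher. The medians of the 3 induced libraries against the knockout mean were -0.332, -0.341 and -0.334. The medians of chromosomes 18 and 17 were -0.16 and -0.13, and those of the remaining chromosomes lay between -0.07 and 0.08. Among genes with a mean of at least 10 CPM, those between 28 and 46 Mb of chromosome 17 had a median of 0.33 and those before and beyond this stretch -0.26 and -0.26. The 14 Mb of chromosome 12 from 98 Mb on had a median of -0.32. These bounds were set after the values were seen. Of the genes named above, Slc38a4, Dab2, Col2a1, Itga5, Krt8, Krt18, Ndrg1 and Rpl37 lie on chromosome 15, T, Cdkn1a, Rps18 and Lama1 on chromosome 17, Gata6, Wnt8a, Dnd1, Cdx1, Bambi, Spry4 and Kif20a on chromosome 18, and Gsc and Rian in the stretch of chromosome 12.

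**Figure D4:**
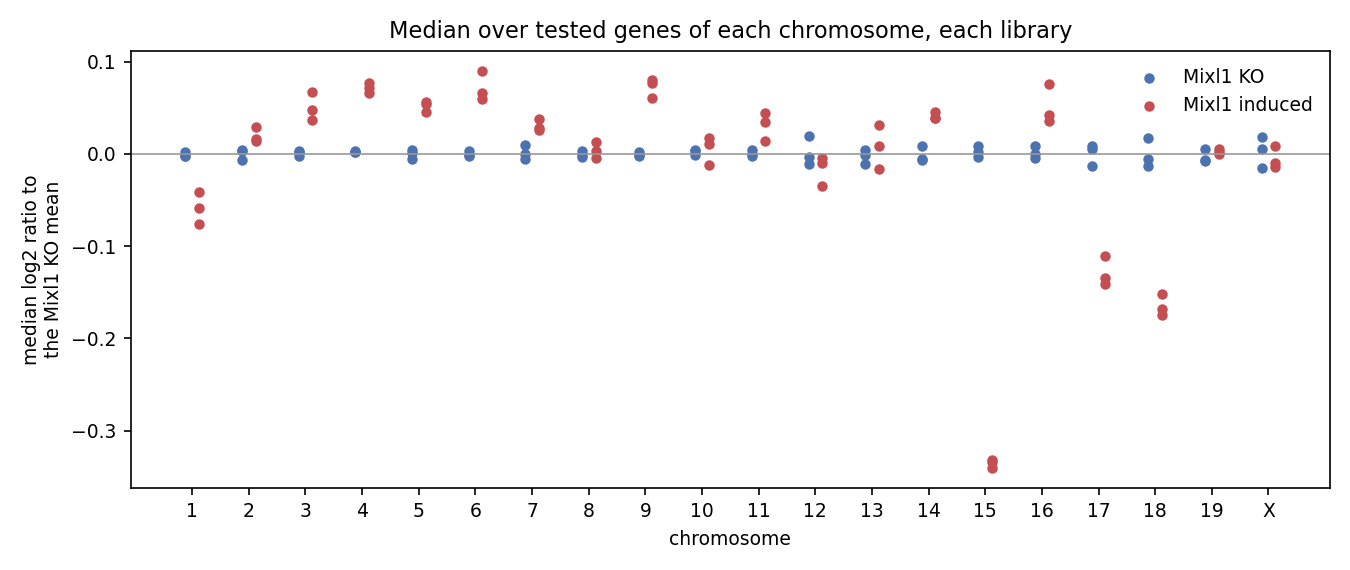
Median log2 ratio of tested genes to the mean of the knockout libraries, by chromosome (x axis), with 1 point per library, knockout in blue and induced in red. The 3 induced libraries lie between -0.341 and -0.332 on chromosome 15.

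In the authors' deposited table, 8725 genes had an adjusted p under 0.05, 4322 higher and 4403 lower. Mixl1 had a log2 fold change of 3.45 in the authors' deposited table and of 3.44 here. Of 14865 genes in both, 4091 were higher and 4051 lower in both; both analyses rest on the same 6 libraries. The log2 fold changes correlated across genes at r = 0.991; genes are not independent replicates. A further 1201 genes were called only by edgeR and 22 only in the authors' deposited table. Gnas, Larp7, Gm12666 and Tmem140 had opposite calls; Gnas was at 1.73 in the authors' deposited table and at -0.31 here. These 4 genes, named after their values were seen, took the sign of the authors' deposited table when counted without regard to strand.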

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

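The counts without chromosomes 15, 17 and 18 and the simulated recovery by expression were the tests chosen here after the data were seen. The comparison of knockout and induced libraries kept its scale under every setting but the test against a 2-fold change, which asks for more and called 1628 genes in place of 9450. Leaving out each library gave 8863 to 9225 genes, with 2552 to 2622 at 2-fold, and a Mixl1 log2 fold change of 3.39 to 3.49. DESeq2 called 8624 genes and limma-voom 9411. Without chromosome 15 genes, 8993 of 14495 passed, and without chromosomes 15, 17 and 18, 8200 of 13326. The 128 other genes named by the fixed rule kept their direction and their side of the threshold in all 1791 recomputed values, and 1 of them was absent under the stricter filter. Genes picked after their values were seen are not among them, and 4 of those, Gnas among them, had opposite calls with the unstranded counts.

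Gene set calls depended most on the test. With an estimated correlation 0 of the 14 lists passed in camera, and fry, which asks another question, called 30; the unadjusted p of camera with an estimated correlation was under 0.05 for 7 of these lists, such as 0.0189 for definitive endoderm. Leaving out a library gave 13 to 15 lists. The blood and endothelial call was lost without knockout replicate 1 and without each induced replicate (adjusted p 0.0532 to 0.112); the cause was not tested. The fibroblast list passed under 5 other camera settings, the NOTCH list under 2 and the naive pluripotency list under 1.

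Chromosome medians moved as expression or calls were restricted. Over genes with at least 10 CPM they were -0.29, -0.11 and -0.18 for chromosomes 15, 17 and 18. Over genes that did not pass the threshold they were -0.0507, -0.0163 and -0.0185, which follows from leaving out the genes that moved.

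The replicate numbers did not clearly pair the libraries, but a weak shared effect is left open. On principal component 2, with 3.06% of the variance, replicate 2 lay at 12.7 (knockout) and 9.56 (induced). Replicate 3 lay at -11.2 and -16.5, and replicate 1 at -1.68 and 7.16. Same-numbered libraries deviated from their group means with correlations of 0.02, 0.15 and 0.13, and the highest correlation of all, 0.17, joined knockout replicate 2 to induced replicate 1. The fit with a replicate block called 9647 genes, 2433 at 2-fold, put Mixl1 at 3.44 and called 15 lists, the fibroblast list being added (adjusted p = 0.0389).

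In the simulated data, small changes of genes with few counts were often missed. Of simulated changes of 0.5 on the log2 scale, 14 of 32 were recovered among genes below the median of 22.6 CPM and 35 of 35 above it. These shares do not carry over to the real comparison, since fewer changed genes make the adjusted p stricter.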

Other observations

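The tests on macrophage genes, imprinted genes, windows of neighbouring genes, GC content and uninduced cells were chosen after the first results were seen. Those on fibroblast genes and splits of the libraries were set before. The bounds for chromosome medians were set before as well, but chromosome 15 and the other autosomes were separated, and the bound for the latter was replaced by the spread of the libraries, after the medians were seen. The genes of the next paragraph were picked after their values were seen.

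Single genes with roles in neurons had large changes in both directions, with no list of them tested. Tlx2, a homeobox gene of enteric and sympathetic neurons, rose from 0.578 ± 0.139 to 39.9 ± 1.75 CPM (SD, n = 3). Nkx6-1 rose from 7.99 to 194.8 CPM, Phox2a from 3.14 to 30.2 CPM, and the axon guidance receptor genes Plxna4 and Robo3 from 3.30 to 83.3 and from 1.51 to 20.1 CPM. Tubb3, a neuronal tubulin gene, rose 3.46-fold, and Penk, a neuropeptide precursor gene, 9.88-fold. Gal, the galanin precursor gene, fell from 32.2 to 1.02 CPM, and Sox3 and Nes fell as well. Secreted inhibitors of WNT also went both ways, Frzb being 4.61-fold and Sfrp1 3.16-fold higher while Notum and Sostdc1 fell. Alox15, a lipoxygenase gene, fell from 578.8 to 36.6 CPM. Hprt, an X-linked gene whose locus is often used for targeted insertions in mouse stem cells, was at 4.01 ± 1.11 CPM in the knockout and 22.8 ± 1.11 CPM in the induced libraries (SD, n = 3). The labels do not say where the inducible construct lies.

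Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the groups, the real one, with 9450, and the highest of the others gave 0. Each other split put libraries of both groups on each side. The difference between the groups then counted as spread within a side, so few calls were possible. With 10 splits the share cannot go under 1 of 10 and so cannot reach 0.05. The splits therefore do not settle whether chance is excluded. At an unadjusted p under 0.05, 9894 genes passed in edgeR between the real groups.

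Macrophage genes differed between the groups. The list of 18 was written after Lyz2, Gpnmb, Spp1, Ctss and Cd68 had been seen to fall, and left these out. All 17 tested members fell, with a median log2 fold change of -2.31, and of -2.46 to -2.19 when each library was left out. Of the genes that prompted the list, and so do not test it, Gpnmb fell from 524.3 to 66.1, Spp1 from 448.1 to 77.4 and Lyz2 from 311.2 to 34.7 CPM. A candidate explanation is that more macrophages, or cells like them, were carried into the knockout samples. The median of -2.31 has the direction this would give, but carry-over sets no size. Since related genes had already been seen to fall, a fall of the list was likely beforehand. A shared source alone would give similar ratios, and the listed members ranged from -1.43 for Laptm5 (SE 0.17) to -3.24 for Cybb (SE 0.26). Arg1 at -5.80 fell further than any listed member. For a carry-over of feeder fibroblasts, 6 fibroblast genes were set to move together past the threshold. Of these 6, Col1a2 and Lum were higher, Col1a1, Postn and Dcn were lower, and Col3a1 did not pass. A different carry-over alone thus does not account for these genes. Carry-over beside other changes is left open, since the differentiating cells can express such genes themselves. Xist (2.81 and 0.507 CPM) and the Y-linked Ddx3y (1.64 and 0.425 CPM) were both lower in the induced group. Beyond the RNA of the listed macrophage genes, whether macrophages were present, and from where, was not tested.

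Among autosomes, chromosome 15 had the median log2 fold change furthest from that of all genes, by -0.33. This was beyond the bound of 0.3 set before the data were examined for a chromosome-wide copy number difference between the lines. Its median was below that of all genes in 8 of 8 windows of 5 Mb with at least 15 genes of at least 10 CPM. The same held in every such window of chromosome 18 (-0.37 to -0.01). Over genes with at least 10 CPM, chromosome 15 had a median of -0.29, and stretches of other chromosomes shifted by similar amounts. Medians were 0.33 between 28 and 46 Mb of chromosome 17, -0.26 on either side, and -0.32 from 98 Mb of chromosome 12 on. The bounds of these stretches were set after the values were seen. Stretches of opposite sign partly cancel in the median of chromosome 17. The size of a shift alone thus does not mark a change of a whole chromosome. GC content and gene length as the cause are argued against, since the difference of chromosome 15 was -0.33 after their correction too. A chromosome-wide copy number difference may thus account for the shift on chromosome 15; its genes lay -0.50, -0.38 and -0.32 from other genes at low, middle and high expression, where 2 copies against 3 in every cell would give -0.58 if expression followed copy number. No other autosome reached the bound of 0.2 set for its absence, but that bound presumed a difference in every cell, and chromosome 18 at -0.17 shifted in each induced library (-0.168, -0.175 and -0.152), so there it cannot be told apart; 30 of 243 windows lay 0.25 or more from the median, 16 of them on chromosomes 15, 17 and 18, against 8 at most in 1000 shuffles (permutation test, p = 0.001, the smallest they can give). A response of chromosome 15 genes to Mixl1 cannot be told apart, because 0 of the 6 libraries are from uninduced cells of the inducible line.

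Several imprinted genes had large changes. Of 24 tested, 8 changed at least 8-fold, 4 of them in 1 cluster on chromosome 12, against 2.70% of all tested genes; they were noticed for their size, so no p-value is given. Meg3, Rian and Mirg of that cluster fell with log2 fold changes of -10.39, -8.98 and -8.66, while their neighbour Rtl1, expressed from the other parental allele, rose by 5.96. Loss of segments that span most genes within 1 Mb of the fallen RNAs, Slc38a4 included, is argued against. The medians of those genes ranged from -0.32 at Grb10 to -0.13 at Rian, above the bound of -0.7 set for such a loss. A loss confined to the RNAs themselves would leave these medians unchanged and was not tested. Meg3, Rian and Mirg lie in 1 cluster, so they are not separate checks. A change of parental imprints between the lines may be involved. In 3 of 5 pairs of neighbours read from opposite alleles, the partners moved in opposite directions past the threshold, which 62.6% of tested genes passed. The log2 fold changes were 10.13 for H19 and -1.57 for Igf2, -10.39 for Meg3 and 5.96 for Rtl1, and 0.47 for Igf2r and -6.39 for Airn. Only Meg3 and Rtl1 both changed at least 8-fold. In the other pairs, Meg3 with Dlk1 and Cdkn1c with Kcnq1ot1, Dlk1 and Kcnq1ot1 did not pass. Airn had 117 reads in the knockout and 1 in the induced libraries, a ratio of 115 (95% counting interval 20.2 to 4572). A change of imprints cannot be told apart from an effect of Mixl1 or doxycycline, since line and Mixl1 differ together and the drug may differ with them.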
